A study of Caenorhabditis elegans with 2 samples.

How the data were processed

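ChIP-seq libraries from 2 biological replicates of eGFP-tagged ZTF-11 in mixed-stage C. elegans embryos (whole organisms, pooled sexes) were analysed from the peak lists the authors deposited. A control library is named in the labels as a possible control and was not analysed here. No extraction protocol was given, and the aligner, the peak caller, their versions and the reproducibility cutoff are not given in the sources used here. The labels give the builds as ce11 and ce10. Per the deposited listing of files, each relaxed list came from 1 replicate's alignments with a control, the pooled list from the alignments of both replicates with a control, and the thresholded list from the pooled list and both relaxed lists by the irreproducible discovery rate. In the ce11 files all 721 thresholded peaks were identical to peaks of the pooled list and were its 721 strongest.

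The values used were the signal value that the authors' caller gave each peak, relative to the control, whose scale is not stated, so that signal was used only to rank, filter and describe peaks within a list. The deposited lists also hold a −log10 q-value for each peak, a meaning taken from the file format, which reached 2.43 in the pooled list and was not used in any test. Neither the read counts nor the depth behind a peak is in the tables used here, so no counting interval is given. Deposited peaks had a fixed maximum width, and 688 of the 721 thresholded peaks were 356 bp wide. No line was identical between the lists of the 2 replicates.

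Coordinates were used on ce11 only, against the WBcel235 assembly, which is the same sequence, and the Ensembl release 115 annotation. All ce11 peak ends fell within the reference chromosomes. The ce10 lists were used only for counts, signal and overlap within that build, and coordinates were never moved between builds. The 23 mitochondrial peaks were left out of the comparisons on features, genes and motifs, and are included in the replicate overlap. The text listings of files hold no measurements and were read for provenance.

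The lists, motifs, tests, naming rule and most alternatives were fixed before the data were examined. A gene was called bound when a thresholded summit lay within 1000 bp upstream to 200 bp downstream of the 5′ end of any of its protein-coding transcripts. Named genes were those nearest to the 20 strongest peaks with their divergent neighbours and nearest non-coding genes, up to 4 bound members of each list with the highest signal, and ztf-11 and unc-119. Names outside this rule are marked where they appear, apart from genes that share or lie near a listed peak and genes in the closing observations. Replicate overlap was the share of the N strongest peaks of replicate 1 that overlapped one of the N strongest of replicate 2 by at least 1 bp, with N set to the 721 thresholded peaks, against 1000 circular shifts per chromosome (one-sided). Features were tested against 1000 random placements of the summits within their chromosomes (one-sided, in both directions), and classes of non-coding RNA genes likewise within 250 bp, a distance chosen after the data were seen. The X chromosome and the 24 gene lists were tested with two-sided Fisher's exact tests, with 95% Woolf intervals for which 0.5 was added to each cell of a table that held a 0. The histone list matched 72 gene identifiers under 50 symbols. Matched random lists (10000 per list) kept the decile of upstream intergenic length, and the smallest two-sided p they can give is 0.0002.

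Motifs (15 sequence patterns) and all 2080 6-mers were counted on both strands. For each, peaks with a match within 50 bp of the summit but none in the flanks were set against peaks with a match in the flanks only, by a two-sided exact binomial test. Flanks had the same total length and started 200 bp from the summit on each side, lengthened so that they held as many start positions as the centre. The ratio is the first count over the second with 0.5 added to both. Benjamini-Hochberg adjustment was made within each family, with a threshold of 0.05. Peaks in the 50 kb around ztf-11 and unc-119 were described as percentiles of 2002 windows, without a test.

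Alternatives were a stricter peak set (signal at or above the median), the strongest peaks of the pooled list, the strongest peaks of each replicate alone, narrower and wider promoter windows (500 bp upstream to 100 bp downstream, 2000 bp to 500 bp), nearest 5′ end only, a background of genes with a pooled summit, matched random lists, motif windows of 25 and 100 bp, dinucleotide-shuffled centres, other rules for overlap (summits within 100 bp, 50% reciprocal overlap, other N) and the ce10 build. Setting a replicate aside meant using the other replicate's strongest peaks. Shuffling made a single copy of each centre, so the p-values against shuffled centres hold no spread from the shuffling.

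The replicate overlap, promoter share, gene list, motif and 6-mer tests were tested on simulated data. With 300 shared peaks planted among 698, the overlap count was 304, and with none planted it was 1. Of 50 random sets of bound genes, 0 had a list past the threshold, and a planted ribosomal protein list was called alone. The random genes were drawn independently, whereas in the data neighbouring genes share peaks, so false calls under such sharing were not tested. Random sequence gave 0 motifs and 0 6-mers, and GAGAGA planted in peak centres ranked 1 among the 6-mers. Simulated centres and flanks had the same base composition, whereas real centres held 50.4% G and C and real flanks 37.4%. Calls that arise from base composition were therefore not tested by the simulation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.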

Results

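ZTF-11 is the C. elegans member of the Myt1 family of zinc finger transcription factors, which act in neurogenesis. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) of an eGFP-tagged ZTF-11 protein in whole mixed-stage embryos of a strain that carries the tagged gene as an integrated transgene in an unc-119 mutant background. The design held 1 group with 2 libraries, which the labels call biological replicates, and no second condition, so the comparisons were between the replicates, between peaks and randomly placed positions, and between lists of genes. The read depth of the libraries is unknown. Each replicate had a relaxed list of 30000 peaks that included background. The peaks called on both replicates together made a relaxed pooled list of 12024 peaks, of which 721 remained in the list thresholded for reproducibility between replicates. Of these, 698 lay on the nuclear chromosomes and 23 on the mitochondrial chromosome. Signal is the authors' own value for each peak, with no replicate error, and it ranged from 33.9 to 938 with a median of 46.4 over the thresholded peaks. All coordinates are of the ce11 build.

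The strongest nuclear peaks lay at promoters, among them those of 2 histone gene pairs and a ribosomal protein gene, and at intergenic sites on the X chromosome. The highest nuclear signal, 266.8, was at chromosome III, 10461201 to 10461445, in the intergenic stretch between atx-2, the ataxin-2 homologue that regulates translation, and its divergent neighbour ecps-1. Its summit was 63 bp upstream of the 5′ end of atx-2. The next, with a signal of 256.1, lay at chromosome I, 9988838 to 9989130, between the divergent histone genes his-67 and his-68, with the promoter window of alg-5, an Argonaute gene, also covering the summit. A further histone pair, his-31 and his-32, had a peak with a signal of 149 at chromosome IV, 8334008 to 8334284. The promoter of tasp-1, which encodes a threonine aspartase homologue, shared a peak with K01G5.10 at chromosome III, 10759134 to 10759329 (signal 184), and rpl-3, a large ribosomal subunit gene, had its summit 269 bp upstream of its 5′ end at chromosome III, 3867478 to 3867653 (signal 137). At 3 intergenic sites on X the signal was 159 (4209182 to 4209386, nearest 5′ end F20B6.9), 151 (11094110 to 11094298, nearest 5′ end W02H3.3) and 134.5 (11937423 to 11937594, nearest 5′ end F55G7.5), and none of the 3 was in a promoter window. The remaining nuclear peaks among the 20 strongest were both on chromosome V. The first, at 11314164 to 11314264, lay in an intron of cutl-18, a cuticlin-like gene, 29 bp from the non-coding RNA gene T03F7.14 (signal 144.5). The second, at 1151422 to 1151598, lay inside the lincRNA gene linc-128, with cmd-1, the calmodulin gene, as the nearest protein-coding 5′ end (signal 139). The other 10 of the 20 strongest peaks were mitochondrial.

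The comparison between replicates asked whether the same sites ranked highest in both libraries. The peaks at atx-2 and at his-67 and his-68 ranked 4 and 5 in replicate 1 and 4 and 3 in replicate 2. Among the 721 strongest peaks of replicate 1, 410 (56.9%) overlapped one of the 721 strongest of replicate 2 by at least 1 bp. Circular shifts of the second list along each chromosome gave a mean of 20.1 shared peaks and at most 33 (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Overlap was 57% among the strongest 100 peaks, 65.3% among the strongest 300 and 36.2% among the strongest 3000. Every one of the 721 thresholded peaks had an overlapping peak in both relaxed lists, from which the thresholded list was itself derived. Best ranks of these overlapping peaks went down to 19210 in replicate 1 and 21951 in replicate 2. Of the 721, 551 were among the 721 strongest of replicate 1, 534 among those of replicate 2 and 404 among both. Across the thresholded peaks the replicates' signal values had a Spearman's rho of 0.421, a value that is limited by the selection on pooled signal and is across peaks, which are not independent replicates. The relaxed lists were called per replicate and the thresholded peaks came from the pooled call, so a thresholded peak is not a call made in each library alone.

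**Figure D1:**
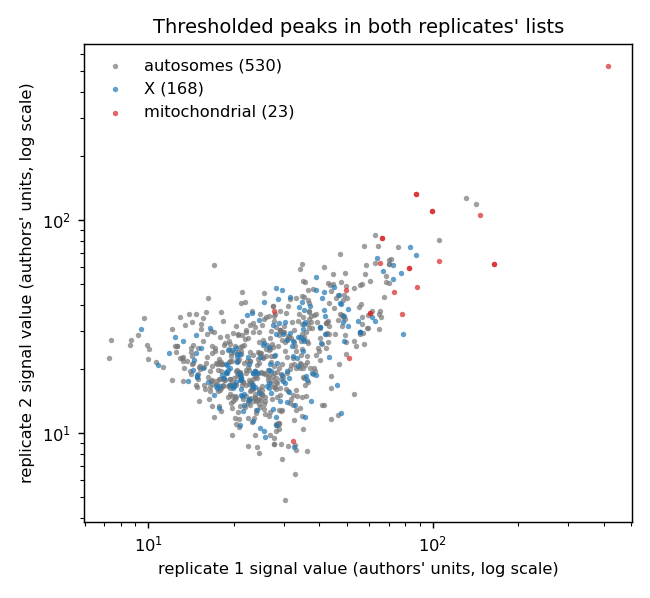
Authors' signal value of each of the 721 thresholded peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for the best overlapping peak of each replicate's relaxed list. Grey points are 530 autosomal, blue points 168 X-linked and red points 23 mitochondrial peaks, and the mitochondrial peak at the upper right is the strongest in both replicates.

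ZTF-11 summits lay upstream of genes and in intergenic DNA far more often than randomly placed positions, and seldom in coding sequence. Of the 698 nuclear summits, 393 (56.3%) were within 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding transcript, against a mean of 178.1 ± 11.6 (SD over 1000 random placements per chromosome), a 2.21-fold excess. Only 10 summits (1.43%) fell in coding exons, where random placement put 24.3%, and 2 fell in 3′ UTRs. Introns held 182 summits (26.1%, random 33.9%), 5′ UTRs 29 (4.15%, random 1.79%), exons of any kind 42 (6.02%, random 29.3%), intergenic DNA 397 (56.9%, random 33.1%) and non-coding genes 120 (17.2%, random 4.604%). Each of these 8 differences had a one-sided permutation p of 0.001, the smallest that 1000 placements can give, and an adjusted p of 0.0020. The 393 promoter summits covered 532 protein-coding genes, since 134 of them lay in the windows of more than 1 gene. Under a window of 500 bp upstream to 100 bp downstream the promoter share was 43.6%, and under 2000 bp upstream to 500 bp downstream 69.2%, both above random placement at the same p.

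**Figure D2:**
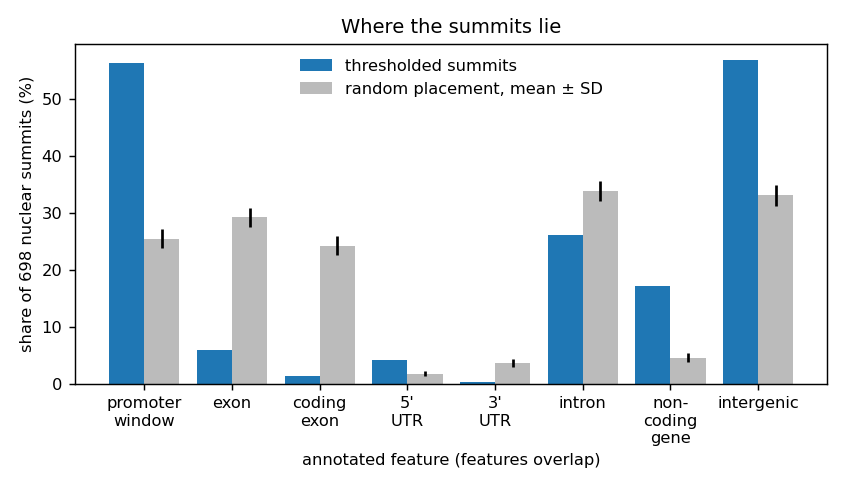
Share of the 698 nuclear thresholded summits in each annotated feature (blue bars, percent) beside the mean share of 1000 random placements with the same number of summits per chromosome (grey bars, error bars 1 SD). Features overlap, so shares do not sum to 100; promoter windows held 56.3% of summits against 25.5% at random, and coding exons 1.43% against 24.3%.

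Genes for small non-coding RNAs were among the sites most often near a summit. Summits lay within 250 bp of a tRNA gene in 58 cases, against a mean of 2.52 for random placement (23-fold), and within 250 bp of a small nucleolar RNA (snoRNA) gene in 44 cases against 1.47 (29.9-fold). Spliceosomal and spliced leader RNA genes (snRNA class) had 9 summits within 250 bp against 0.470, microRNA genes 10 against 1.00, and the broad class of other short non-coding RNA genes 191 against 29.5. Within 100 and 500 bp, distances chosen after the data were seen, the excess was 44.3-fold and 13.8-fold for tRNA genes, 46.4-fold and 18.7-fold for snoRNA genes and 35.7-fold and 11.1-fold for the snRNA class. At 250 bp tRNA, snoRNA, snRNA, microRNA and other short RNA genes each passed the one-sided permutation test (p = 0.001, the smallest that 1000 placements can give; adjusted p = 0.0018). Several of these genes lay inside introns. The strongest summit near a tRNA gene was at chromosome I, 6781648 to 6782003, in an intron of cye-1, which encodes cyclin E (signal 79.2), and a summit at chromosome II, 11960653 to 11961008, lay 67 bp from the snoRNA gene W03C9.9 (signal 122.5). The spliced leader RNA genes sls-2.4 and sls-2.2 held summits with signals of 97.2 and 75.7. These examples were chosen after their values were seen. Germline piRNA genes, with 5 nearby summits against 20.4, and pseudogenes, with 6 against 25.8, had fewer than random placement (adjusted permutation p = 0.0045), and for piRNA genes the ratio of 0.245 was 0.0830 within 100 bp and 0.440 within 500 bp. No summit was near an rRNA gene (random mean 0.139), and lincRNA genes had 5 nearby summits against 2.52 (adjusted permutation p = 0.162). Many tRNA genes exist in near-identical copies, and a median of 16.8% of the 32-bp words of the tRNA-associated peaks occurred elsewhere in the genome.

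Among the nuclear chromosomes X held the most peaks per megabase. It had 168 peaks, or 9.48 per Mb, against 6.42 per Mb over the autosomes, where chromosome I had 8.82, III 8.42, II 7.33, IV 5.37 and V 3.58. Among X-linked protein-coding genes 91 of 2731 (3.33%) had a summit in the promoter window, and among autosomal genes 441 of 17242 (2.56%). The odds ratio was 1.31 (95% interval 1.04 to 1.65, two-sided Fisher's exact p = 0.0249 over genes). By chromosome, the share of genes bound was 3.79% on I and 3.60% on III, both above X. It was 2.64% on II, 2.35% on IV and 1.38% on V, all below X. The excess on X was thus over the autosomes combined, not over each autosome. Of the X-linked peaks 85 of 168 (50.6%) lay in promoter windows, as did 308 of 530 autosomal peaks (58.1%), a difference that did not pass the test (odds ratio 0.738, 95% interval 0.521 to 1.05, Fisher's exact p = 0.0906). The excess of bound X-linked genes lost significance without replicate 2 (odds ratio 1.24, exact p = 0.0868), with the stronger part of the peaks (1.27, p = 0.148) and with the window of 500 bp upstream to 100 bp downstream (1.265, p = 0.0875).

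Gene lists asked which kinds of genes had a summit in the promoter window, over 24 fixed lists and 19973 protein-coding genes. Ribosomal protein, histone, heat shock and DREAM and MuvB genes were bound more often than other genes, and chemoreceptor genes less often. Of the 78 ribosomal protein genes 20 (25.6%) were bound, led by rpl-3, rps-28 (signal 111), rpl-15 (96.45) and rpl-35 (94.9), against 2.57% of other genes. Their odds ratio was 13.05 (95% interval 7.79 to 21.9, adjusted p = 2.57e-13, Fisher's exact test with Benjamini-Hochberg adjustment). The 20 genes rested on 19 peaks, and without replicate 1 the odds ratio was 8.58. Most of these peaks also lay in the window of a gene of another kind, such as Y41D4B.4 at rps-28 and K11H12.8 at rpl-15, so the assignment is shared. With each peak given only to its nearest 5′ end, the odds ratio was 6.27 (exact adjusted p = 1.05e-05). Of the 72 histone genes 12 (16.7%) were bound through 7 peaks (odds ratio 7.45, 95% interval 3.99 to 13.9, exact adjusted p = 3.24e-06), most of them divergent pairs such as his-67 and his-68. The histone odds ratio was 15.7 with the stronger part of the peaks and 3.34 with each peak given only to its nearest 5′ end. The heat shock list had 5 of 22 genes bound (odds ratio 10.8, 95% interval 3.98 to 29.5, exact adjusted p = 0.00114). These were hsp-3, an endoplasmic reticulum chaperone (chromosome X, 6092036 to 6092391, signal 124), the mitochondrial chaperone gene hsp-60 (92.2), hsp-1, which encodes a cytosolic Hsp70 (76.7), hsp-110 (61.2), which shares its peak with rpn-3, and, outside the naming rule and chosen after its value was seen, hsp-90 (41.4). With each peak given only to its nearest 5′ end, the heat shock list no longer passed (odds ratio 3.09, exact adjusted p = 0.363).

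DREAM is a cell cycle repressor complex whose MuvB core is reported as a partner of ZTF-11, which is why its subunits formed a list. Of its 8 genes 5 were bound (odds ratio 61.5, 95% interval 14.65 to 257.9, adjusted p = 4.14e-06, Fisher's exact test). The bound genes were lin-54, whose product binds DNA (chromosome IV, 13240507 to 13240862, signal 65.2), the histone-binding subunit gene lin-53 (chromosome I, 9619863 to 9620218, 45.6), the E2F gene efl-1 (chromosome V, 16965679 to 16966034, 41.96), the retinoblastoma homologue lin-35 (chromosome I, 5807311 to 5807666, 40.6) and lin-9 (chromosome III, 8904099 to 8904454, 35.5), the last outside the naming rule. All 5 summits were intergenic. The peaks of lin-54, lin-53, efl-1 and lin-35 also lay in the windows of rpl-12, nra-2, fbxa-90 and vps-51, so the assignment to the DREAM gene is shared. The odds ratio was 25.3 without replicate 1 and 23.4 without replicate 2 (exact adjusted p = 0.003885 and 0.00386). In the strongest peaks of replicate 1 alone lin-54, lin-53 and lin-35 were bound, and in those of replicate 2 alone efl-1, lin-35 and lin-9. The list did not pass with the stronger part of the peaks (odds ratio 10.7, exact adjusted p = 0.345) or with each peak given to its nearest 5′ end (10.3, adjusted p = 0.0836).

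Chemoreceptor genes, the large family of sensory receptors, had 5 of 1171 members bound (0.427%, against 2.80% of other genes, odds ratio 0.149, 95% interval 0.0615 to 0.360, exact adjusted p = 6.89e-08). The 5 were sre-1, sre-23, sri-5, srrt-1 and srh-269, the last outside the naming rule, and sri-5 and srrt-1 were not bound without replicate 1. The srh-269 summit lay inside a tRNA gene, and the sre-23 summit 83 bp from the snoRNA gene ZK265.10. The peaks of sre-1, sri-5 and srrt-1 also lay in the windows of B0495.9, rsr-1 and let-504, so their assignment is shared. srrt-1 is not a chemoreceptor gene but shares the name pattern, and without the 14 such names the list had 4 bound members (odds ratio 0.120, exact adjusted p = 1.54e-08). Against only those genes with a pooled relaxed summit in their window the difference did not pass the test (odds ratio 0.541, exact adjusted p = 0.794).

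The lists of neurogenesis factors, terminal selectors, neuropeptides and pan-neuronal genes did not pass the test in either direction in these embryos. None of the 16 neurogenesis transcription factor genes (odds ratio 1.10, 95% interval 0.0662 to 18.45, and 4.41 with the nearest 5′ end only), the 28 terminal selector genes (0.640, 0.0390 to 10.5) or the 102 neuropeptide genes (0.177, 0.0110 to 2.86) had a thresholded summit in the window. These intervals are wide, and so the lists are too short for a lower share to be detectable or a higher one to be excluded. Of 30 pan-neuronal and synaptic genes 2 were bound, syd-2 (signal 55.2), which encodes a liprin of the presynaptic zone, and maco-1 (47.4; odds ratio 2.62, exact adjusted p = 0.435). The pan-neuronal odds ratio was 4.76 with the nearest 5′ end only (exact adjusted p = 0.0555) and 5.39 with the stronger part of the peaks (adjusted p = 0.279). Against only genes with a pooled relaxed summit in their window it was 1.65. The body muscle list had 3 of 31 genes bound, unc-112 (68.5), act-4 (36.97) and unc-60 (35.1), with an odds ratio of 3.93 and an exact adjusted p of 0.167. Single members were bound in the glia list (lit-1, 34.5, 1 of 18), the germline list (mex-1, 43.5, 1 of 23) and the list of Hox genes and cofactors (ceh-20, 39.7, 1 of 10), with odds ratios of 2.15, 1.66 and 4.07. The lists of Wnt pathway genes (sys-1, 36.8, and lit-1, 2 of 27), cell cycle genes (the Cdk inhibitor gene cki-1, 51.3, and the spindle checkpoint gene bub-1, 38.2, 2 of 31), proteasome genes (rpn-3 and rpn-7, 48.0, 2 of 33) and ceh homeobox genes (ceh-38, 40.1, and ceh-20, 2 of 63) had odds ratios of 2.93, 2.53, 2.36 and 1.20. Nuclear hormone receptor genes had 4 of 269 bound, nhr-48 (53.4), nhr-49 (39.7), nhr-47 (34.5) and nhr-255 (34.4), an odds ratio of 0.548 with an exact adjusted p of 0.576. The nhr-255 summit lay inside a tRNA gene. No gene was bound in the lists of 24 intestine (odds ratio 0.744, 95% interval 0.0452 to 12.25), 32 epidermis (0.561, 0.0343 to 9.17), 17 pharynx (1.04, 0.0626 to 17.35), 24 Notch pathway (0.744, 0.0452 to 12.25), 25 hlh (0.715, 0.0435 to 11.8) or 156 collagen genes (0.116, 0.00720 to 1.86, exact adjusted p = 0.0947). None of these lists passed the test. Several of their odds ratios moved by over 1.5 times when 1 library was left out, without passing. Without replicate 1 they were 4.675 for pan-neuronal and synaptic genes (4.33 without replicate 2), 2.795 for neurogenesis factors, 4.51 for cell cycle, 1.61 for Wnt pathway, 1.75 for hlh and 0.269 for collagen genes. Without replicate 2 they were 1.84 for Hox genes and cofactors, 1.95 for ceh and 0.288 for nuclear hormone receptor genes. Of the genes named, act-4, bub-1, rpn-7, ceh-20, nhr-49 and nhr-47 were not bound without replicate 2, mex-1 and sys-1 not without replicate 1, and nhr-255 with neither replicate alone. With each peak given to its nearest 5′ end, the Wnt (odds ratio 7.05, exact adjusted p = 0.0110) and cell cycle (5.96, adjusted p = 0.0157) lists did pass. Against only genes with a pooled relaxed summit in their window, the odds ratios of these lists were 1.24 and 0.824, and neither passed. The p-values and intervals of all lists are over genes, which are not independent because neighbours share peaks, and do not test replicates.

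**Figure D3:**
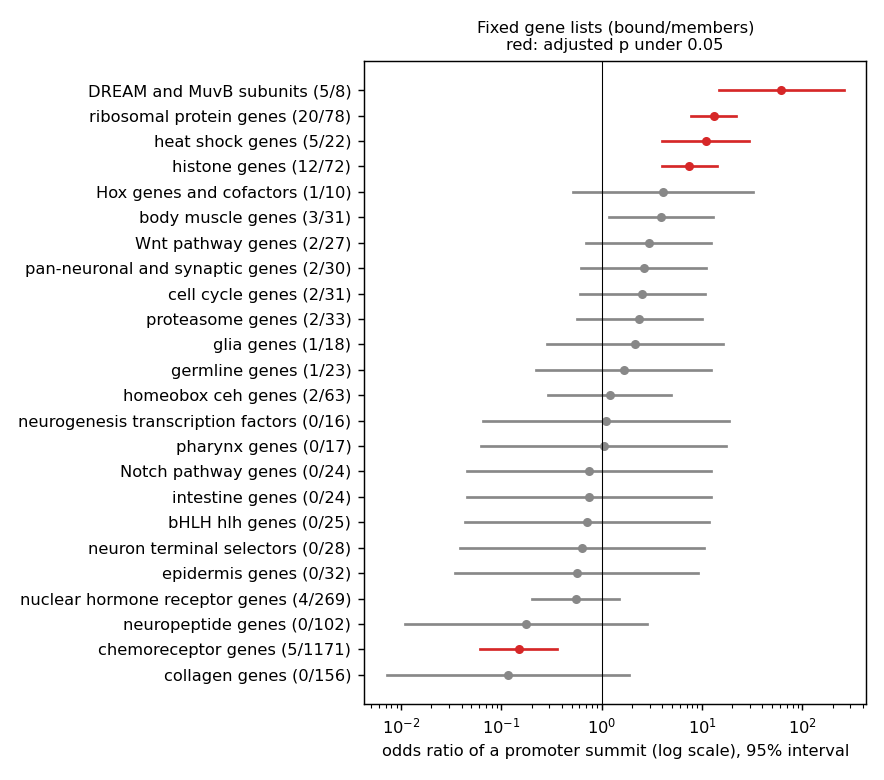
Odds ratio of a thresholded summit in the promoter window for each of the 24 fixed gene lists against all other protein-coding genes (points, log axis), with 95% intervals (lines) and the bound and total members in brackets. Red marks lists with an adjusted p under 0.05, of which DREAM and MuvB, ribosomal protein, heat shock and histone genes lie above 1 and chemoreceptor genes below 1.

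The sequence around the summits asked which known elements sat at the peak centres. GAGA repeats were within 50 bp of the summit in 202 of 698 peaks (28.9%) and in the flanks of the same peaks in 74 (10.6%). Of the discordant peaks 177 had a repeat only in the centre and 49 only in the flank, a ratio of 3.59 (95% interval 2.62 to 5.06, adjusted p = 5.11e-17, exact binomial test). The C. elegans M1 promoter element, TCTGCGTCTCT, was central in 32 peaks and in the flank of 1 (exact adjusted p = 2.97e-08), and the B box, an internal promoter element of RNA polymerase III genes, was central in 26 and in the flank of 1 (adjusted p = 1.04e-06). Of the 26 B boxes, 21 were in peaks near tRNA genes and 4 in peaks near snoRNA genes. Without replicate 1 the B box ratio was 7.80 and without replicate 2 it was 47.0, against 17.7, and without replicate 2 the M1 ratio was 63.0 against 21.7. GC boxes (10.3% against 3.72%, ratio 3.04) and E-boxes (41.4% against 28.8%, ratio 1.71), the sites of basic helix-loop-helix proteins, were also more often central (exact adjusted p = 2.34e-06 and 2.82e-06), as were E2F sites (9.17% against 2.87%, ratio 3.26, adjusted p = 2.34e-06). The E2F excess was lost against dinucleotide-shuffled copies of the same centres (ratio 1.14, exact adjusted p = 0.602).

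The Myt1 family core AAGTTT was less frequent at summits than in the flanks. It was central in 28 peaks (4.01%) and in the flank of 108 (15.5%), a ratio of 0.242 (95% interval 0.147 to 0.371, exact adjusted p = 5.54e-12), and the longer AAAGTTT gave 2.15% against 6.88% (ratio 0.305, adjusted p = 4.08e-05). Peak centres were richer in G and C (50.4%) than their flanks (37.4%) and the genome (35.4%). Against shuffled centres of the same dinucleotide makeup neither sequence differed in frequency at the test's threshold, with ratios of 0.662 (exact adjusted p = 0.185) and 1.07 (adjusted p = 1.00). For AAAGTTT the call was also lost within 25 bp of the summit (ratio 0.515, exact adjusted p = 0.207). The CHR element bound by LIN-54 (17.3% against 30.9%, ratio 0.459, exact adjusted p = 1.30e-08) and the homeobox core (2.87% against 6.02%, ratio 0.429, adjusted p = 0.00523) were also less central than flanking, but both turned to more central against shuffled centres (ratios 1.97 and 2.73, adjusted p = 5.64e-04 and 0.0261). GATA sites were less central under both controls (1.86% against 8.60% in flanks, ratio 0.223, exact adjusted p = 6.92e-08; ratio 0.443 against shuffled centres). AP-1 sites were central in 1 peak and flanking in 8 (ratio 0.176, exact adjusted p = 0.0488), a call that was lost when either replicate was left out (ratio 0.368, adjusted p = 0.1825 without replicate 1 and ratio 0.474, adjusted p = 0.308 without replicate 2). The AP-1 call was also lost with the stronger peaks at a similar ratio (0.20, exact adjusted p = 0.625) and within 25 bp (0.429, adjusted p = 0.721), and held within 100 bp (0.371, adjusted p = 0.0372) and against shuffled centres (0.143, adjusted p = 0.0195). FoxA (ratio 0.811, exact adjusted p = 0.121), SOX (0.815, adjusted p = 0.357) and T-box sites (0.818, adjusted p = 1.00; 1.31 without replicate 2) did not pass the test against the flanks within 50 bp of the summit. Within 100 bp FoxA (0.763, exact adjusted p = 0.0171) and SOX sites (0.741, adjusted p = 0.0359) were less central than flanking, although FoxA sites were more central against shuffled centres (1.44, adjusted p = 0.0163) and SOX sites less (0.554, adjusted p = 0.00214).

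**Figure D4:**
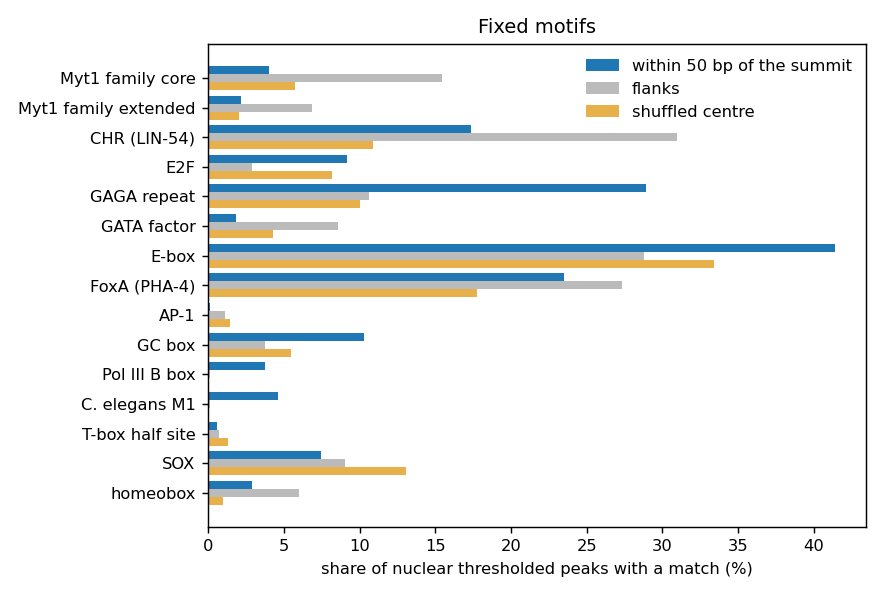
Share of the 698 nuclear thresholded peaks (x axis, percent) with at least 1 match to each fixed motif within 50 bp of the summit (blue), in the flanks of the same total length (grey) and in a dinucleotide-shuffled copy of the centre (orange). GAGA repeats stood at 28.9% in centres against 10.6% in flanks and 10.03% in shuffled centres, while AAGTTT stood at 4.01%, 15.5% and 5.73%.

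Among all 2080 6-mers, 373 were more often central than flanking and 284 less often, at an adjusted p under 0.05 (exact binomial test). The more central ones were led by AGAGAG (25.4% against 8.31% of peaks, ratio 4.09), GAGAGA, CGCACA (15.6% against 2.87%, ratio 6.74) and GCGCGC (10.7% against 0.860%, ratio 16.3), and held on average 4.16 G or C bases. The less central ones were led by AAAAAT (13.3% against 46.8%) and held on average 1.28 G or C bases. Without replicate 2 the ratio of CGCACA was 4.12. Against shuffled centres 86 6-mers were more central, 62 of them among the 373, and GAGAGA, AGAGAG, AGAGAC and CACACA led. The ratios of CGCACA and GCGCGC were then lower (2.20 and 2.55) and that of GAGAGA higher (6.18 against 3.59 with flanks). The ratio of GCGCGC was 29.7 with the stronger peaks and 9.17 within 100 bp.

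The ztf-11 region itself was examined because the strain carries the tagged gene as an additional transgene. The gene, on the minus strand of chromosome I at 9904303 to 9910545, had no thresholded summit in its promoter window. The closest thresholded summit lay 3508 bp from the nearest 5′ end of any of its transcripts. That end need not be the outer end of the gene at 9910545, and this summit may be the one beyond the 3′ end given below. In the 50 kb around ztf-11 (9882424 to 9932423) the pooled list had 19 peaks, more than 99.65% of the 2002 windows of that size in the genome, whose median was 5. Replicates 1 and 2 had 27 and 28 peaks there, against window medians of 15 and 14, and the thresholded list had 3. The strongest of them, with a signal of 57.9 and rank 232, had its summit at 9904147, 156 bp beyond the 3′ end of ztf-11. At unc-119, a neuronal gene that is mutant in this strain and serves as the usual rescue marker in such lines (chromosome III, 10902641 to 10908935), no thresholded peak lay in the gene or in the 50 kb around it. Its pooled window count of 11 was above 89.71% of windows, and those of replicates 1 and 2 were 23 (92.1%) and 24 (93.4%). The nearest pooled summit was 13 bp from the nearest 5′ end of any unc-119 transcript.

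The same libraries were also processed on the ce10 build. The thresholded list held 725 peaks there and 721 on ce11, a ratio of 1.01, and the pooled list 12054 and 12024. The strongest signal was 938 in both builds, and the share of strong peaks in common between replicates was 56.6% in the ce10 lists.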

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

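The test of mitochondrial coverage was chosen only after the result was seen, while the tests on gene copies and on base composition were set beforehand. Mitochondrial peaks stood out as signal outside the nuclear comparisons. There were 23 thresholded peaks on the mitochondrial chromosome, 3.19% of the list, and 10 of them were among the 20 strongest, including the strongest peak in both replicates, inside ND5 at 12322 to 12645 with a signal of 938. Their median signal was 93.2, against 45.8 for nuclear peaks. A candidate explanation is a raised read depth along the whole mitochondrial chromosome relative to the control, as mitochondrial copy number differs between preparations. The thresholded peaks covered 48.9% of its 13794 bases, between the values set as evidence for (over 50%) and against (under 20%), and the pooled peaks, for which no value was set, 53.9%, so raised depth and local enrichment cannot be told apart without the control's reads. No biological explanation was tested.

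The peaks at histone, tRNA and snoRNA genes belong to families with several gene copies, where reads shared between copies could pile up. This is argued against for histone promoters and snoRNA genes: the median share of a peak's 32-bp words that occur elsewhere in the genome was 0% in both, and 6 of 7 histone peaks and 39 of 44 snoRNA peaks had no such word. For tRNA genes it stays open. The median was 16.8% (quartiles 14.85% and 17.77%), none of the 58 peaks was over 50%, and only 1 had no such word. A tRNA gene fills a small part of a peak, so copies of the gene alone could hardly reach 50%. The shortfall from that value therefore does not argue against shared reads. The tRNA genes with copies were near a summit more often (62 of 528) than those without (3 of 84). The odds ratio was 3.59 (95% interval 1.10 to 11.7, Fisher's exact p = 0.0214). Genes with copies may also differ from single ones in their use by the cell, which was not tested. No biological explanation was tested for this pattern, and whether other tagged factors or the tag alone give peaks at the same sites was not analysed here.

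The Myt1 family core AAGTTT was rarer at summits than in flanks, the opposite of what binding through this sequence would give. Base composition of the centres is a candidate explanation: against dinucleotide-shuffled centres the ratio moved from 0.242 (95% interval 0.147 to 0.371) to 0.662 (0.371 to 1.14), and the call ended. The remaining ratio is still below 1 with an interval that includes 1, so neither a deficit nor an excess of the core at summits was shown. No biological explanation was tested.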

How the results depend on the processing

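The alternatives chosen only after the data were seen were the nuclear-only replicate overlap, the gene lists without summits near tRNA, snoRNA and snRNA genes, the trimmed chemoreceptor list and the 100 and 500 bp distances to non-coding genes. Replicate overlap was between 47.1% and 61.9% under the alternatives (65.3% among the strongest 300 peaks and 36.2% among the strongest 3000) and the promoter share between 43.6% and 69.2%, all above chance under the alternatives run for each, and the strongest pooled peaks were the thresholded peaks themselves, so that setting moves nothing. The X-linked odds ratio fell short of the threshold with the stricter peaks (1.27, exact p = 0.148) and with the 500 bp window (1.265, p = 0.0875), and ranged from 1.24 (without replicate 2) to 1.51 (without replicate 1). The number of more central 6-mers, 373, was 521 within 100 bp, 187 with the stricter peaks, 183 within 25 bp, 86 against shuffled centres and 272 to 323 with one replicate left out. Reversed against shuffled centres were CHR (ratio 1.97) and the homeobox core (2.73). FoxA, which had not passed against the flanks, passed there as more central (1.44). The stricter set has fewer peaks, and shuffled copies keep the base composition of the centres, which the flanks do not. The causes of these and the other changes were not tested. Of the 373, 178 were called again with the stricter peaks, 174 within 25 bp and 62 against shuffled centres. Where a setting could change them, 211 of 217 list values, 76 of 90 motif values and 17 of 18 non-coding values were counted as unchanged. Unchanged meant the same side of the threshold and, where both passed, the same direction. Most lists did not pass in the main test, and values that passed in neither setting counted as unchanged whatever their direction. Of the others 4 list and 8 motif values no longer passed, 2 and 3 newly passed, and lincRNA genes passed at 500 bp (2.51-fold). The 4 list losses were 2 for DREAM and MuvB and 1 each for heat shock and chemoreceptor genes. The other 3 motif values were those of CHR, FoxA and the homeobox core. Adjusted p-values ranged over the alternatives from 1.20e-06 to 0.345 for the DREAM and MuvB list, 7.94e-04 to 0.363 for heat shock genes, 5.40e-09 to 0.794 for chemoreceptor genes, 2.25e-17 to 0.0012 for ribosomal protein genes and 3.87e-09 to 0.0355 for histone genes. The value of 0.0012 came from the matched random lists, at the smallest p they can give. For ribosomal protein genes the highest adjusted p from Fisher's exact test was 1.48e-04, against genes with a pooled summit. Histone and ribosomal protein genes passed under the 9 alternatives that could change them, but with odds ratios down to 3.34 and 3.72. No paired analysis was possible because the design holds 1 group. Unknown read depth limits all comparisons of signal.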

Other observations

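The scan over gene name classes and the search for GCGCAGGG in thresholded peaks were chosen only after the data were seen; the test in the remaining pooled peaks was set before its result. Among 175 name classes with at least 10 members, 8 had more bound promoters than other genes and 0 had fewer (Fisher's exact test with Benjamini-Hochberg adjustment). In the fixed lists even 0 of 156 collagen genes gave an unadjusted Fisher's exact p of 0.0237. Fewer bound promoters could therefore hardly be called in smaller classes, and no conclusion is drawn from the 0. The rpl, rps, his and hsp classes repeat the fixed lists. The dnj class, which encodes DnaJ co-chaperones of Hsp70, had 6 of 29 genes bound (dnj-29, dnj-14, dnj-12, dnj-13, dnj-9 and dnj-19, odds ratio 9.63, exact adjusted p = 0.003425). The cox class, nuclear genes for subunits of mitochondrial cytochrome c oxidase, had 4 of 15 bound (cox-5B, cox-5A, cox-6B and cox-6A, odds ratio 13.4, exact adjusted p = 0.0134). The sec class, whose members act in protein translocation and secretion, had 4 of 19 bound (sec-61.G, sec-15, sec-61.B and sec-3, odds ratio 9.81, exact adjusted p = 0.0307). The lin class, named for cell lineage defects, had 9 of 47 bound (odds ratio 8.79, exact adjusted p = 1.53e-04), among them the heterochronic gene lin-28 and the chromatin genes lin-59, lin-61 and lin-40 beside the DREAM and MuvB genes lin-54, lin-53, lin-35 and lin-9; lin-66 was the last. These tests are over genes and rest on 4 to 9 genes per class. Some of the peaks also lay in the windows of other genes, such as nhr-47 at dnj-19 and bub-1 at lin-61, so these assignments are shared. No alternative setting was run for the name classes.

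Several of the strongest X-linked peaks lay away from promoters and carried GCGCAGGG, a core of the sequence at which the worm dosage compensation complex is recruited to X. Within 50 bp of the summit it occurred in 8 of 168 X-linked thresholded peaks (4.76%) and in 1 of 530 autosomal ones (0.189%), an odds ratio of 26.5 (95% interval 3.28 to 213, Fisher's exact p = 7.07e-05). The 8 peaks included the intergenic sites at 4209182 to 4209386 and 11094110 to 11094298, an intron of mom-1 (6296384 to 6296739), a coding exon of pks-1 (5429370 to 5429725) and an intergenic site 4921 bp upstream of xol-1, the switch gene of sex determination (8036335 to 8036452). Of the 8, 6 lay outside promoter windows. In the pooled peaks that were not thresholded, the sequence was near the summit in 6 of 2070 X-linked and 6 of 9230 autosomal peaks (odds ratio 4.47, 95% interval 1.44 to 13.9, Fisher's exact p = 0.0126). The genome holds 4.57 such sites per Mb on X and 2.82 on the autosomes, a difference smaller than either odds ratio's estimate but within the second interval. A hypothesis is that part of the X-linked signal may come from dosage compensation recruitment sites, whether by ZTF-11 itself or because such sites give signal in many immunoprecipitations; these were not told apart, and no peaks of the complex were analysed here.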
